A study of Coptotermes formosanus x Coptotermes gestroi and Coptotermes formosanus and Coptotermes gestroi with 67 samples.

How the data were processed

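Workers of Coptotermes formosanus, C. gestroi, Hybrid F and Hybrid G were compared at 3 molting stages in head and body (thorax and abdomen without gut). Per the labels' protocols, RNA was extracted with Trizol and silica columns and libraries were made with an mRNA library kit. Per the submitters' processing notes, Bowtie2, RSEM and DESeq2 were used; their versions and roles, and the genome build and annotation, are not given in the sources used here. The deposited table holds expected counts per gene (estimated counts with decimals, 27.7% of the values not whole), with totals that differ between profiles as unscaled counts do, and a gene length. RSEM-type expected counts divide reads that fit several genes among them, so genes with near-identical copies are uncertain.

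All columns of a group were identical (0 of 15950 genes differed in any of the 24 groups), and totals grew with the number of columns of a group, so each group was used as 1 profile. Total counts per profile were 9861833 to 38338701, with between 12967 and 14469 genes counted. NA stood in 8.22% of the cells (3339 genes with any) and was read as no reads. NA cells of inter-molt and pre-molt profiles fell in the same genes in 8 of 8 cross and tissue pairs. Where the post-molt profile had NA, the inter-molt profile had no count in 6 of 8 pairs and the pre-molt profile in 2 of 8. No column was without a sample. Intervals and floors (3 counts, 95% Poisson intervals) cover counting error only.

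The design fixed before the data were examined assumed separate samples per group and a fit on group means. With 1 profile per group that fit has no residual degrees of freedom. In its place 1 additive model of cross and stage was fitted per tissue to 12 profiles (6 residual degrees of freedom), which gives stage contrasts with crosses as blocks and cross contrasts with stages as blocks. Within a tissue, stage by cross and the stage effect of a single cross leave no residual degrees of freedom. They were fitted to all 24 profiles, with head and body as the replicates of each cross and stage and tissue terms for each cross and stage (6 residual degrees of freedom; a correlation between head and body of the same cross and stage is ignored), and each cross was set against the other 3 within a tissue (4 residual degrees of freedom); these fits were added after the data were seen. Within a cross and tissue, genes with at least a 4-fold range of log2 CPM (prior count 2) are counted with no p. Stage by hybrid status was tested with 4 residual degrees of freedom. The p-values measure how a difference recurs over crosses or stages in these profiles. They do not measure the spread between workers or colonies, and a stage effect that differs between crosses counts as error.

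Expected counts were rounded to whole numbers, filtered with filterByExpr by stage (12845 genes kept in the head and 13046 in the body), scaled by TMM and tested with edgeR 4.0.16 (estimateDisp, glmQLFit with robust = TRUE, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Genes outside both parents are those called against both with the same sign. Named IDs are, by a rule fixed beforehand, the 2 per direction with the largest fold change among genes past the threshold with the same sign in all crosses (or stages) and a mean log2 CPM of at least 3; for genes outside both parents, examples from those with the smallest larger p; for stage by cross, the 4 with the smallest p. Cfor_09914 was chosen after its values were seen, as was the rule for the genes that part the hybrids, which takes the 4 with the smallest adjusted p in the head. CPM values are TMM-scaled, with SD over the crosses or stages compared. In the stage and cross contrasts, the SE given is the absolute log2 fold change divided by the square root of the quasi-likelihood F. It approximates the SE of the fitted coefficient. As no table pairs the IDs with names, the 23 gene lists and the cell type markers matched 0 genes and no list was tested.

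The tests were checked on counts simulated from these profiles with 200 changed genes. In head pre-molt against inter-molt, 0.5% of 1.5-fold, 60% of 2-fold and 85.5% of 4-fold changes were recovered, and in the body 0%, 17.5% and 78%. With 4-fold changes, 13 of 184 head calls and 12 of 168 body calls were false, more than the 5% aimed at. For the species contrast, 54% of 2-fold changes were recovered in the head and 2.5% in the body. Each rate is from a single draw with 200 changed genes. The threshold on adjusted p is less strict when more genes change. Recovery can therefore be higher where far more genes were called, as between the species. Alternatives fixed beforehand were the median-of-ratios (RLE) scaling, no filter, DESeq2 1.42.0, the hybrids alone for body contrasts with inter-molt, and each cross alone. Leaving out each profile, leaving out genes with NA, thinning all profiles to the smallest total of the tissue, a filter that asks for counts at all stages, and tissue as the only block term were added after the data were seen.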

Results

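RNA was sequenced from workers of 2 subterranean termites, Coptotermes formosanus and Coptotermes gestroi, and of 2 hybrids between them that the labels call Hybrid F and Hybrid G. Workers were taken before a molt (pre-molt), after a molt (post-molt) and between molts (inter-molt), and heads and bodies were sequenced separately, the body being thorax and abdomen without the gut. The labels list 67 samples in 24 groups of cross, tissue and stage, with 3 samples in 21 groups, 2 in the pre-molt C. gestroi body and 1 each in the inter-molt bodies of C. formosanus and C. gestroi. The columns of the samples of 1 group were identical in every gene (0 genes differed in any group), so they were counted as 1 profile per group and the table held 24 profiles. No spread between samples of a group could be measured. Totals ran from 9861833 counts in the inter-molt C. gestroi body to 38338701 counts in the pre-molt C. formosanus body, and the other group with 1 column, the inter-molt C. formosanus body, had 10080438 counts. Divided by the number of columns, totals lay between 7215931 and 12779567 counts. A gene without a count could have had up to 3 counts by counting error alone. In these profiles that is between 0.0783 and 0.304 CPM (counts scaled to a common total). This range uses totals without TMM scaling, unlike the other CPM values.

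The table held 15950 genes, 12000 with a Cfor number, 3949 with a BGI_novel number and 1 with another name. The deposited table gave no gene names, so genes are given by ID, without a known function, and none of the 23 gene lists fixed before the data were examined (molting hormone, cuticle, muscle, digestion and others) matched a gene. Over 13534 genes, stage took 32.6% of the sum of squares of log2 CPM, cross 26.7%, tissue 20.9%, and the remainder was 19.7%. In the head the first principal component held 40.5% of the variance and set inter-molt profiles (-135.1 to -86.1) apart from post-molt (8.48 to 24.5) and pre-molt profiles (76.3 to 105.1). The second held 26.1% and ran from C. gestroi through both hybrids to C. formosanus. In the body the inter-molt profile of Hybrid G lay at -24.5 on the first component, to the right of the post-molt C. gestroi body (-35.3), and the other inter-molt profiles between -150.4 and -94.0.

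**Figure D1:**
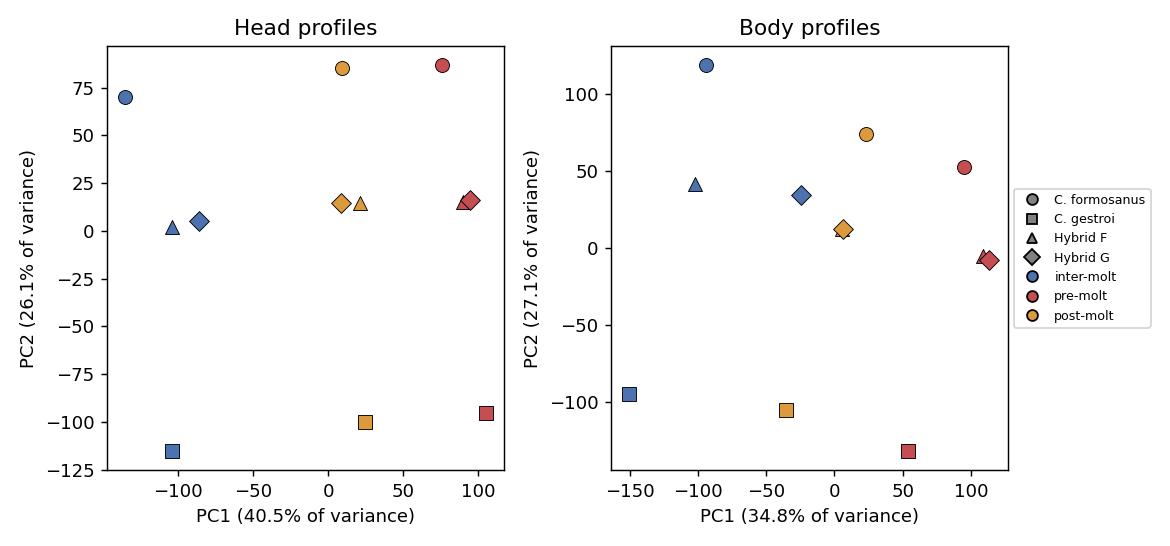
Scores of the 12 head profiles and the 12 body profiles on the first and second principal components of log2 CPM, each axis with its percent of variance; the shape gives the cross and the color the stage. Inter-molt heads lie at the left and pre-molt heads at the right. Among bodies, the inter-molt Hybrid G profile (-24.5) lies to the right of the post-molt C. gestroi profile (-35.3).

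The first comparison asked which genes differ between molting stages, with the 4 crosses as blocks. In the head, 6456 of 12845 genes differed between pre-molt and inter-molt workers, 3138 higher and 3318 lower before the molt (edgeR quasi-likelihood test, adjusted p under 0.05). Increases were the larger changes: 468 genes were at least 16-fold higher and 117 at least 16-fold lower. Cfor_12028 rose from 0.271 ± 0.207 CPM to 5777 ± 927.5 CPM (SD, n = 4 crosses), a log2 fold change of 14.40 ± 0.70 (SE, edgeR adjusted p = 4.8e-06). Cfor_09910 rose from 2.78 ± 3.90 to 13165 ± 6365 CPM, a log2 fold change of 12.85 ± 1.09 (edgeR adjusted p = 5.7e-05). Cfor_08132 fell from 939.3 ± 319.3 to 5.53 ± 2.83 CPM and Cfor_12414 from 300.8 ± 176.8 to 2.40 ± 1.44 CPM, with log2 fold changes of -7.49 ± 0.46 and -7.14 ± 0.51 (edgeR adjusted p = 1.4e-05 and 2.6e-05). Cfor_09914 had the highest count of all genes in each of the 8 pre-molt profiles, between 2.63% and 8.06% of all counts.

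Post-molt heads differed from inter-molt heads in 6216 genes, 3068 higher and 3148 lower. BGI_novel_G001906 rose from 13.9 ± 26.6 to 5703 ± 676.5 CPM (n = 4 crosses), a log2 fold change of 11.52 ± 1.85 (edgeR adjusted p = 0.0015), and BGI_novel_G001909 from 113.6 ± 224.0 to 13469 ± 4985 CPM, a log2 fold change of 11.16 ± 2.31 (edgeR adjusted p = 0.0051). Hybrid G carried most of their inter-molt level, at 53.8 and 449.6 CPM, against 0.151 to 1.41 and 0.407 to 3.41 CPM in the other crosses, so the ratios of pooled counts were lower, at 473.2 and 137.8 (log2 8.89 and 7.11). Cfor_11787 fell from 756.3 ± 427.8 to 1.57 ± 1.17 CPM and Cfor_03103 from 2077 ± 966.7 to 6.99 ± 4.43 CPM. Between post-molt and pre-molt heads 3396 genes differed, 1699 higher and 1697 lower after the molt, and at least 16-fold changes were mostly decreases (222 lower, 22 higher). Cfor_12830 fell from 1232 ± 789.3 to 0.868 ± 0.143 CPM and Cfor_08155 from 888.6 ± 175.1 to 1.12 ± 0.552 CPM. BGI_novel_G002829 rose from 1534 ± 1104 to 36480 ± 7213 CPM, and Cfor_11731 from 6.61 ± 3.94 to 156.1 ± 86.6 CPM (edgeR adjusted p = 0.029 and 0.030). These last increases had adjusted p of up to 0.126 and 0.118 when 1 profile was left out.

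**Figure D2:**
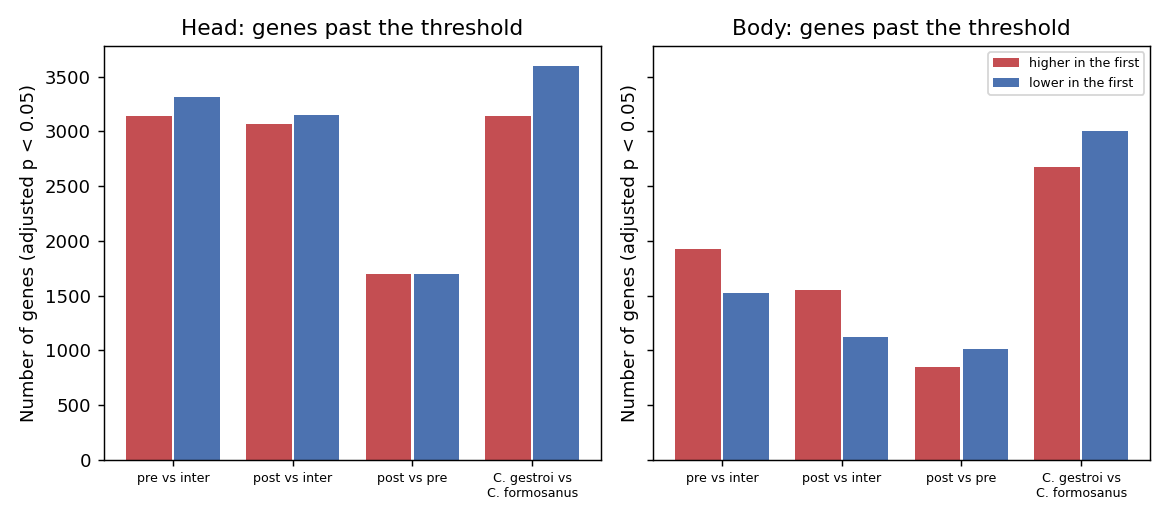
Number of genes past an edgeR adjusted p of 0.05 in head and body, higher (red) and lower (blue) in the first-named group, for the 3 stage comparisons and for C. gestroi against C. formosanus. The pre-molt against inter-molt comparison gave 6456 genes in the head and 3455 in the body.

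In the body, 3455 of 13046 genes differed between pre-molt and inter-molt workers, 1928 higher and 1527 lower, with 453 at least 16-fold higher and 179 at least 16-fold lower. Cfor_08092 rose from 0.336 ± 0.419 to 1827 ± 1484 CPM (n = 4 crosses), a log2 fold change of 12.29 ± 0.84 (edgeR adjusted p = 0.00014). Cfor_12830, which also led the head decreases after the molt, rose from 0.334 ± 0.245 to 1639 ± 876.4 CPM before it (log2 fold change 11.92 ± 0.76, edgeR adjusted p = 0.00012). Cfor_02543 fell from 1571 ± 1637 to 0.497 ± 0.560 CPM and BGI_novel_G001371 from 5032 ± 5669 to 2.43 ± 3.57 CPM, with log2 fold changes of -11.25 ± 1.33 and -11.11 ± 1.04 (edgeR adjusted p = 0.00099 and 0.00044). Post-molt and inter-molt bodies differed in 2668 genes, 1547 higher and 1121 lower. BGI_novel_G002923 and BGI_novel_G002924 rose from 0.0364 ± 0.0421 and 0.0832 ± 0.0383 CPM to 1508 ± 1313 and 1424 ± 1149 CPM. The inter-molt profiles held 5 counts of BGI_novel_G002923 in all, so its pooled ratio of 27655 had a 95% counting interval of 11851 to 85173. Cfor_02543 and BGI_novel_G001371 were also the most decreased genes after the molt, at 1.74 ± 1.08 and 4.53 ± 3.83 CPM. Post-molt and pre-molt bodies differed in 1858 genes, 843 higher and 1015 lower, led by decreases of Cfor_08096 (4455 ± 3085 to 4.45 ± 1.93 CPM) and Cfor_08092 (1827 ± 1484 to 2.19 ± 1.33 CPM). BGI_novel_G001363 rose from 9.06 ± 17.8 to 115.9 ± 141.0 CPM and BGI_novel_G003362 from 3.21 ± 3.49 to 87.1 ± 44.0 CPM (edgeR adjusted p = 0.018 and 0.035). C. gestroi carried most of the pre-molt level of BGI_novel_G001363, at 35.8 CPM, against at most 0.409 in the other crosses, and both adjusted p passed 0.05 when some single profiles were left out (up to 0.062 and 0.101). The body counts moved more with single profiles than the head counts did. Pre-molt against inter-molt gave 2164 and 2283 genes without the inter-molt or the pre-molt Hybrid F profile. Post-molt against inter-molt gave 1648 genes without post-molt C. formosanus, 1397 without inter-molt Hybrid F and 1384 without post-molt Hybrid F. Post-molt against pre-molt gave 1125 and 1197 genes without post-molt and pre-molt C. formosanus, 785 and 827 without post-molt and pre-molt Hybrid F, 924 and 1217 without post-molt and pre-molt Hybrid G, and 3155 by DESeq2. The hybrids alone, whose inter-molt bodies had 3 columns each, gave 1865 genes before and 920 after the molt against inter-molt. Without the inter-molt Hybrid G profile, the pre-molt against inter-molt count was 3362.

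Genes were sorted by the stage at which they stood highest or lowest, counting those called against both other stages with at least 2-fold changes. In the head 558 genes were highest before the molt, 325 after it and 654 between molts, and 241, 121 and 1083 genes were lowest at these stages. In the body 476, 184 and 335 genes were highest and 217, 83 and 595 lowest in the same order. A gene can count as highest at 1 stage and lowest at another. Profiles simulated without a stage effect gave at most 0 such genes in 5 draws per tissue. With no stage effect in any gene few calls arise at all, so this 0 was nearly fixed in advance. It leaves out genes that truly differ from 1 stage, which need only 1 false call. Independent calls against both other stages would give 95.3 genes highest before the molt in the head and 62.2 in the body. Both calls use the same pre-molt profiles, so part of the excess may come from that. Among 12538 genes tested in both tissues, 349 were highest before the molt in head and body, where independent lists would share 20.4, and 204 were highest between molts in both, against 14.1. Of the genes that differed between pre-molt and inter-molt workers, 1494 were higher in both tissues (468.7 for independent lists), 939 were lower in both (352.6), and 67 went in opposite directions (830.3). Across all 12538 genes tested in both tissues, which are not independent, the log2 fold changes of head and body had r = 0.83 and rho = 0.57 before against between molts.

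Within 1 cross and 1 tissue a stage difference has no test, since each stage is 1 profile, so sizes are given. In the head, 2493 of 12845 genes covered at least a 4-fold range over the 3 stages in C. formosanus, 2359 in C. gestroi, 2007 in Hybrid F and 1974 in Hybrid G. In the body the numbers were 2489, 2715, 2310 and 2231 of 13046 genes. With each cross taken alone and counts required at all stages these fell to 1676, 1461, 1385 and 1270 in the head. In the body they fell to 1629, 1416, 1560 and 1427. The order of the crosses stayed the same in the head but changed in the body, so there it depends on these settings. With head and body taken as the replicates of each cross and stage, edgeR called stage differences in the mean of both tissues in 4512 of 13534 genes in C. formosanus, 4194 in C. gestroi, 3976 in Hybrid F and 3618 in Hybrid G. The Hybrid F count was 2123, 2453 and 2500 without its inter-molt, post-molt and pre-molt bodies and 2311 and 2508 without its inter-molt and post-molt heads. The Hybrid G count was 2100, 2337 and 2092 without its inter-molt, post-molt and pre-molt bodies and 2157 without its pre-molt head. The labels do not say that heads and bodies came from different workers, and the fit takes them as independent, so p can be too small if they share workers. Across genes, the pre-molt against inter-molt changes of any 2 crosses correlated with r between 0.80 and 0.84 in the head and between 0.54 and 0.76 in the body. For post-molt against inter-molt changes in the body r ran from 0.38 (C. gestroi and Hybrid G) to 0.74 (C. formosanus and Hybrid F).

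The labels set crosses within a species against crosses between species, so the stage response of both hybrids was tested against that of both parental species. edgeR called 0 genes in the head and 0 in the body, with 754 head genes and 540 body genes at an unadjusted p under 0.05, where 642.3 and 652.3 would be expected by chance. DESeq2's likelihood ratio test called 160 and 150 genes. Without the inter-molt Hybrid F head, edgeR called 15 head genes. With 4 residual degrees of freedom the head test recovered 52.5% of simulated 4-fold differences, with 16 false calls among 121. The body test recovered 0% in a single draw, so its count of 0 does not show that such differences are absent. Each cross was then set against the other 3 within a tissue (4 residual degrees of freedom). edgeR called 19 head genes for C. formosanus, 0 for C. gestroi, 0 for Hybrid F and 7 for Hybrid G, and 3, 2, 0 and 28 body genes. The test recovered 27.5% of simulated 4-fold changes in Hybrid F heads and 0% in bodies, so a count of 0 does not show that a difference is absent. At an unadjusted p under 0.05 there were 1441, 1381, 220 and 404 head genes (642.3 by chance) and 888, 2020, 86 and 659 body genes (652.3). These chance levels take p as uniform. Stage responses that differ among the crosses set together count as error, so counts can fall below them, as for Hybrid F (220 and 86). DESeq2 called 451, 436, 45 and 188 head genes and 274, 699, 7 and 283 body genes. No statement rests on these counts, since leaving out 1 profile gave 0 to 23 and 0 to 10 head genes for C. formosanus and Hybrid G, and 1 to 3, 0 to 6 and 0 to 33 body genes for C. formosanus, C. gestroi and Hybrid G.

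Differences between the 4 crosses in stage response, in the mean of head and body, were tested over all 24 profiles, with head and body taken as independent replicates of each cross and stage (6 residual degrees of freedom). edgeR called 296 of 13534 genes, with 2125 at an unadjusted p under 0.05 (676.7 by chance), and DESeq2 called 1764. The test recovered 33.5% of simulated 4-fold changes in 1 cross. Each value here is 1 profile. Cfor_03163 stood higher before than after the molt in C. formosanus, at 45.9 and 9.88 CPM in the head and 67.8 and 8.14 in the body, and lower before than after it in C. gestroi, at 28.7 and 114.6 CPM in the head and 43.7 and 88.2 in the body (edgeR adjusted p = 0.00025). BGI_novel_G001607 stood at 163.2 CPM in the inter-molt head and 243.3 in the inter-molt body of Hybrid G, and at 0 to 0.581 CPM in the inter-molt profiles of the other crosses (edgeR adjusted p = 0.00031). Cfor_12891 stood at 60.5 and 80.0 CPM in the inter-molt head and body of Hybrid G and at 1.02 to 2.54 CPM in those of the other crosses (edgeR adjusted p = 0.00052). Cfor_11986 stood at 17.0 and 10.8 CPM in these Hybrid G profiles, 5.62 and 3.91 in C. formosanus, 2.28 and 1.80 in Hybrid F and 0.0755 and 0.0906 in C. gestroi (edgeR adjusted p = 0.00031, but 0.187 with tissue as the only block term). Heads and bodies may come from the same workers, so a difference between crosses cannot be parted here from one between the groups of workers sampled, and the p-values can then be too small. With tissue as the only block term 140 genes were called. The count was 180, 125 and 176 without the inter-molt, post-molt and pre-molt C. formosanus bodies and 140 without the post-molt C. formosanus head, 116 and 126 without the post-molt C. gestroi body and head, 113, 100 and 133 without the inter-molt, post-molt and pre-molt Hybrid F bodies and 133, 103 and 127 without the heads, and 191, 120 and 84 without the inter-molt, post-molt and pre-molt Hybrid G bodies and 110 and 91 without the post-molt and pre-molt heads.

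The second comparison asked which genes differ between the species at matched stages, with the 3 stages as blocks. In the head 6743 of 12845 genes differed, 3143 higher and 3600 lower in C. gestroi than in C. formosanus. In the body 5684 of 13046 genes differed, 2677 higher and 3007 lower. The genome and annotation used for counting are not given, so differences in how reads of each species were assigned cannot be told apart from expression. C. gestroi heads had NA in 1445 to 1465 genes and C. formosanus heads in 1272 to 1317. In bodies these were 1692 to 1984 and 1455 to 1577. BGI_novel_G000505 stood at 86.4 ± 23.4 CPM (SD, n = 3 stages) in C. gestroi heads and had no count in the 3 C. formosanus heads, where the table holds NA. If NA means no reads, which the sources do not say, it is at least 2941-fold higher against a floor of 3 counts over the group. The same holds for each gene given below with NA in a species. In the body it stood at 71.9 ± 18.9 CPM, at least 1995-fold higher. BGI_novel_G003060 had NA in all C. gestroi profiles and 3119 ± 1938 CPM in heads and 2634 ± 548.3 CPM in bodies of C. formosanus, at least 83756-fold and 48849-fold lower in C. gestroi. BGI_novel_G001359 reached 2449 ± 2424 CPM in C. gestroi bodies with NA in those of C. formosanus (at least 67917-fold higher), BGI_novel_G001574 1044 ± 577.9 CPM in C. gestroi heads (0.132 ± 0.137 CPM in C. formosanus), and Cfor_02400 120.5 ± 14.0 CPM in C. formosanus bodies with NA in those of C. gestroi. BGI_novel_G001611 stood at 1094 ± 1821 CPM in C. formosanus heads and had NA in those of C. gestroi. The excess of genes lower in C. gestroi lay among the BGI_novel numbers, with 662 higher and 1222 lower in the head, against 2481 higher and 2378 lower among the other genes. It grew with the size of the difference, from 53.4% of all called head genes to 67.5% of those with at least 16-fold differences. Head and body shared 2122 genes higher and 2468 genes lower in C. gestroi (635.4 and 832.7 for independent lists), and 16 had opposite directions.

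The third comparison set each hybrid against each parental species. Hybrid F differed from C. formosanus in 2429 head genes (1253 higher, 1176 lower) and 1374 body genes (866 higher, 508 lower), and from C. gestroi in 4333 head genes (2405 higher, 1928 lower) and 4494 body genes (2529 higher, 1965 lower). Hybrid G differed from C. formosanus in 1885 head genes (1073 higher, 812 lower) and 897 body genes (656 higher, 241 lower), and from C. gestroi in 3529 head genes (2151 higher, 1378 lower) and 3686 body genes (2244 higher, 1442 lower). Both hybrids had fewer called genes against C. formosanus than against C. gestroi in each tissue; this difference of counts was not tested. Of the genes with at least 2-fold species differences in the head, the hybrids stood between the parents in 89.1% to 94.1%, and in the body in 83.8% to 88.2%. The same parental profiles chose these genes and set the range, so a high share is partly built in. On a scale of CPM from the lower parent (0%) to the higher parent (100%), genes higher in C. gestroi had medians of 41.0% in Hybrid F and 41.3% in Hybrid G heads, and genes higher in C. formosanus 52.3% and 51.4%. In the body the medians were 35.7% and 36.7% for genes higher in C. gestroi and 57.2% and 57.0% for those higher in C. formosanus. Read assignment that differs between the species could also shift these positions and counts, and this was not tested. Counts of hybrid against C. formosanus depended on single profiles and on depth. In the head, Hybrid F gave 1494 and 1392 genes without inter-molt and pre-molt C. formosanus and 884, 1015 and 1116 without its own inter-molt, post-molt and pre-molt profiles, and against C. gestroi 2778 and 2843 without its inter-molt and post-molt profiles. Hybrid G heads gave 1226 and 1133 without post-molt and pre-molt C. formosanus, 847, 912 and 829 without their own inter-molt, post-molt and pre-molt profiles, 2903 by DESeq2, and against C. gestroi 2121 and 2120 without their inter-molt and pre-molt profiles. In the body, Hybrid F against C. formosanus gave 520 and 637 without post-molt and pre-molt C. formosanus, 431, 403 and 410 without its own inter-molt, post-molt and pre-molt profiles, 861 without post-molt Hybrid G, 500 with all profiles thinned to the smallest total, and 2890 by DESeq2 (1462 higher, 1428 lower). Against C. gestroi it gave 2933, 2739 and 2401 without its own inter-molt, post-molt and pre-molt profiles. Hybrid G bodies against C. formosanus gave 414 and 376 without post-molt and pre-molt C. formosanus, 554 and 498 without inter-molt and post-molt Hybrid F, 511, 375 and 371 without their own inter-molt, post-molt and pre-molt profiles, 339 after thinning, and 2378 by DESeq2 (1321 higher, 1057 lower). Against C. gestroi they gave 1903 without their pre-molt profile and 2433 after thinning.

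Genes outside the parental range were those called against both parents with the same sign. In the head, 118 genes of Hybrid F lay outside, 43 above and 75 below both parents, and 39 of Hybrid G, 21 above and 18 below. In the body, 181 genes of Hybrid F lay outside, 115 above and 66 below, and 70 of Hybrid G, 61 above and 9 below. Hybrids simulated at the parental mean gave between 2 and 10 such genes in 5 draws per tissue. That setting can understate chance, since a hybrid at the level of 1 parent, not simulated, needs a false call against that parent alone. Independent lists would share 234.6 genes above and 176.5 below in Hybrid F heads, and 179.7 and 87.1 in Hybrid G heads. In bodies these were 167.9 and 76.5 for Hybrid F and 112.8 and 26.6 for Hybrid G. All real counts lay below these levels. A hybrid between the parents is called with opposite signs against them, which lowers the overlap, so these levels do not measure chance. How many genes chance gives stays open. Cfor_01364 stood at 24.2 ± 13.4 CPM in Hybrid F heads, against 7.64 ± 3.83 in C. formosanus and 9.28 ± 4.36 in C. gestroi (n = 3 stages). Cfor_06221 stood lower in Hybrid F than in both parents in both tissues, at 16.7 ± 0.701 CPM in the head against 30.9 ± 7.34 and 39.9 ± 4.50. BGI_novel_G003806 reached 79.4 ± 8.99 CPM in Hybrid G heads against 33.6 ± 0.926 and 2.29 ± 0.556. In the body, Cfor_11522 reached 164.9 ± 42.7 CPM in Hybrid F against 85.9 ± 9.86 and 67.9 ± 13.3, and Cfor_00777 reached 27.9 ± 13.3 CPM in Hybrid G against 13.3 ± 8.19 and 12.02 ± 4.59. These counts moved with the tool, the depth and single profiles. DESeq2 gave 241 and 99 genes in Hybrid F and Hybrid G heads and 563 and 328 in bodies, with 249 of the 563 above both parents in Hybrid F bodies, and the median-of-ratios scaling gave 97 above and 104 below there. Hybrid F heads gave 19, 34 and 36 genes without their own inter-molt, post-molt and pre-molt profiles, 57 and 51 without inter-molt and pre-molt C. formosanus, 71 without pre-molt C. gestroi and 74 without pre-molt Hybrid G. Hybrid G heads gave 19 and 13 without their own inter-molt and pre-molt profiles, 21 without pre-molt C. formosanus, 24 without post-molt C. gestroi and 21 without post-molt Hybrid F. Hybrid F bodies gave 26, 26 and 21 without their own inter-molt, post-molt and pre-molt profiles, 49 and 46 without post-molt and pre-molt C. formosanus, 82 and 107 without post-molt and pre-molt Hybrid G, and 56 after thinning. Hybrid G bodies gave 29, 43 and 24 without their own inter-molt, post-molt and pre-molt profiles, 34 and 20 without post-molt and pre-molt C. formosanus, 34, 32 and 40 without inter-molt, post-molt and pre-molt Hybrid F, and 29 after thinning.

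The hybrids differed from each other in 19 head genes, 12 higher and 7 lower in Hybrid G, and in 16 body genes, 10 higher and 6 lower. At an unadjusted p under 0.05 there were 1507 head and 895 body genes (642.3 and 652.3 by chance), and DESeq2 called 272 and 135, so the number of genes that part the hybrids is not settled. The species contrast of the same fit recovered 54% of simulated 2-fold changes in the head and 2.5% in the body. In both tissues 11 genes were called, all with the same sign in head and body. Cfor_04911 stood at 89.1 ± 17.8 CPM in C. formosanus heads and 72.8 ± 19.96 CPM in Hybrid F heads (n = 3 stages), but at 0.227 ± 0.170 CPM in C. gestroi and 0.194 ± 0.157 CPM in Hybrid G, a log2 difference between the hybrids of -8.56 ± 0.36 (Hybrid G minus Hybrid F, edgeR adjusted p = 7.1e-05). Cfor_05466 went the other way in level, at 394.5 ± 83.8 CPM in C. gestroi heads and 372.6 ± 116.0 CPM in Hybrid G heads but at 3.48 ± 0.999 CPM in C. formosanus and 3.66 ± 0.794 CPM in Hybrid F (log2 difference 6.63 ± 0.28, edgeR adjusted p = 7.1e-05). These 2 genes had the smallest adjusted p, but most genes were sorted the other way. Of the 18 head genes that also differed between the species, the difference between the hybrids put Hybrid F on the C. gestroi side in 15 and on the C. formosanus side in 3, which include Cfor_04911 and Cfor_05466; in the body these were 11 and 4 of 15. The side is read from the signs alone, and a hybrid may lie outside both parents. The next 2 genes by adjusted p lie on the C. gestroi side. Cfor_03330 stood at 20.4 ± 2.81 CPM in C. gestroi heads and 23.3 ± 3.45 in Hybrid F heads, against 8.13 ± 0.529 in C. formosanus and 5.67 ± 0.359 in Hybrid G (log2 difference -2.03 ± 0.11, edgeR adjusted p = 0.00025). Cfor_01127 stood at 1.04 ± 0.129 CPM in C. gestroi and 2.60 ± 0.342 in Hybrid F, against 14.997 ± 1.21 in C. formosanus and 14.5 ± 2.34 in Hybrid G (log2 difference 2.48 ± 0.16, edgeR adjusted p = 0.00081). The head count fell to 12 without post-molt C. gestroi, to 7, 8 and 6 without the inter-molt, post-molt and pre-molt Hybrid F profiles and to 5, 8 and 5 without those of Hybrid G. The body count was 13 without inter-molt C. gestroi, 6, 8 and 6 without inter-molt C. formosanus, pre-molt C. gestroi and post-molt C. gestroi, 6 and 7 without pre-molt and post-molt C. formosanus, 4, 6 and 5 without inter-molt, post-molt and pre-molt Hybrid F, 7, 9 and 3 without those of Hybrid G, and 5 after thinning. Cfor_04911 and Cfor_05466 kept an adjusted p under 0.05 in each of these refits. In the head, Cfor_03330 and Cfor_01127 kept it too, but in the body Cfor_03330 lost its call in 11 of 12 refits without 1 profile (adjusted p up to 0.247) and Cfor_01127 in 4 (up to 0.091), and both lost it after thinning (adjusted p = 0.264 and 0.210).

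**Figure D3:**
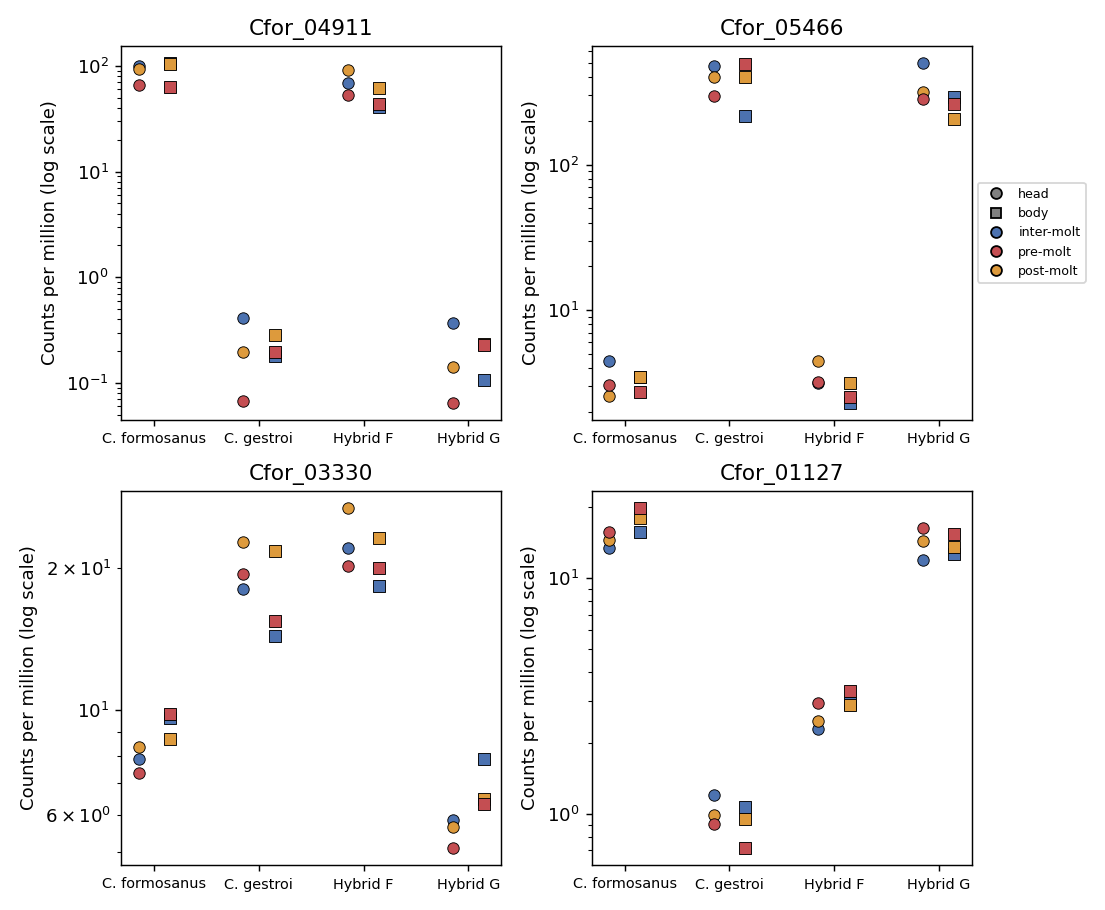
CPM (log axis) in each of the 24 profiles of the 4 genes with the smallest adjusted p between the hybrids in the head, by cross, with circles for heads, squares for bodies and the color for the stage. For Cfor_04911 Hybrid F lies with C. formosanus and Hybrid G with C. gestroi, with head means of 72.8 and 0.194 CPM in the hybrids; for Cfor_01127 Hybrid G lies with C. formosanus.

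Genes that were high before the molt stood at a higher level in the inter-molt Hybrid G body than in the other inter-molt bodies. The same genes were taken for all crosses, by a rule set after the data were seen that leaves out the inter-molt profiles (a mean of at least 20 CPM before the molt, at least 30-fold above the mean after it, and at least 10 CPM before it in each cross). In the body, the median level of these 118 genes at inter-molt was 0.0643% of the same cross's pre-molt level in C. formosanus, 0.106% in C. gestroi, 0.228% in Hybrid F and 2.11% in Hybrid G (quartiles 0.525% and 10.01%). In the head the medians of 132 genes were 0.0612%, 0.0616%, 0.181% and 0.196%. The median counts of these genes at inter-molt were 3, 4, 16 and 59.5 in the body and 6, 4.5, 9 and 10 in the head (same order). The body percentages of the parental species thus lie near the floor of 3 counts and are imprecise. Each is 1 profile, so the difference has no test.

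**Figure D4:**
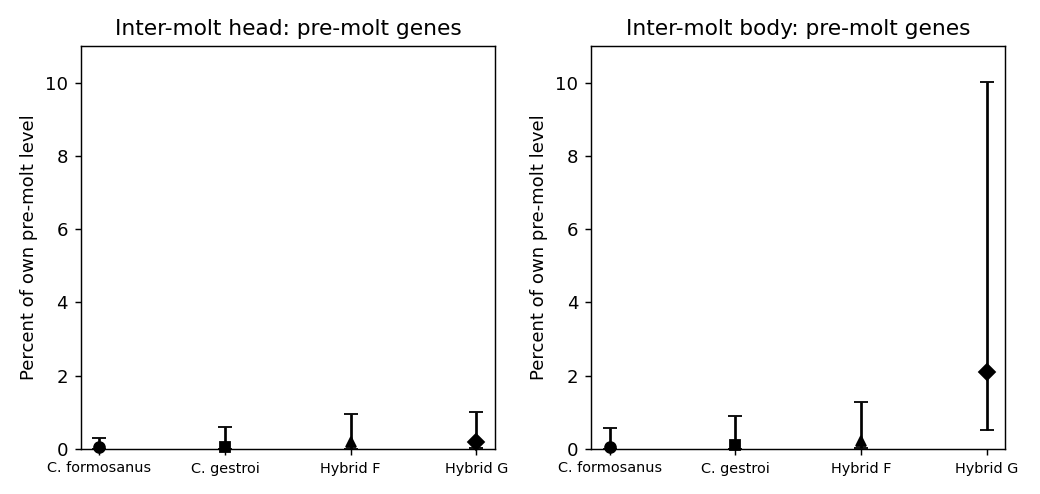
Level of pre-molt genes in the inter-molt profile of each cross, in percent of the pre-molt level of the same cross, in head and body; points are medians over the same genes for all crosses and bars run from the lower to the upper quartile. The inter-molt body of Hybrid G has a median of 2.11%, and the other bodies lie between 0.0643% and 0.228%.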

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

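The tests of splits, and all tests on the inter-molt Hybrid G body and on the genes that part the hybrids, were chosen after the results were seen; the tests on neighbouring ID numbers were set before theirs.

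In each tissue and stage the 4 crosses were compared on depth, composition and stage measures, 36 sets in all, of which chance would flag about 1 in 20 (1.8 sets). A profile far from the other 3 was found in 2 sets, about the number that chance would give. The measure of pre-molt genes used a rule set after the data were seen, so the rate of 1 in 20 does not hold for it. In the pre-molt C. gestroi body, which has 2 columns, 13348 genes had a count, against 14190 to 14319 in the other pre-molt bodies. In the inter-molt Hybrid G body, pre-molt genes stood at a median of 2.105% of their pre-molt level, against 0.0643% to 0.228% in the other crosses.

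The inter-molt Hybrid G body holds transcripts of pre-molt genes that the other inter-molt bodies have at far lower levels. The gap to the next cross took 0.920 of the range, and 0.641 on a log2 scale over the genes highest before the molt, where it did not pass Dixon's 95% limit for 4 values. Reads of a pre-molt body library mixed in stay open. At least 37.3% of these genes lay below the counting limit around 1 common fraction of each of the 4 pre-molt bodies as source, but that limit leaves out the spread between libraries, which the group profiles do not give. Workers at a point before a molt that was not sampled could also have been pooled in. A difference in depth is not needed for it, since the gap was 0.904 with all bodies thinned to 9861834 counts. That some Hybrid G inter-molt workers were nearer to a molt stays open. The head gap was only 0.112, and on the log2 scale Hybrid F heads (-3.94) stood above Hybrid G heads (-4.04). On the first principal component, however, the inter-molt Hybrid G head (-86.1) lay nearest the other stages (other inter-molt heads -135.1 to -103.8). Single stage genes also stood higher in it, as BGI_novel_G001607 at 163.2 CPM, against at most 0.581 in the other inter-molt heads. That gene was named for its small p in the stage by cross test of these same profiles, so it adds no separate evidence. BGI_novel_G001906, named for its rise after the molt, also stood higher in this head, at 53.8 CPM against at most 1.41 in the other crosses. The labels do not say whether heads and bodies came from the same workers.

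Of the genes called between the hybrids, in some each hybrid lies near 1 of the parents, and in others a hybrid lies outside both, as for Cfor_06221 in both tissues. Profiles of a hybrid mixed with or swapped for a parent would shift all species genes, but the hybrids' median positions between the parents differed by at most 0.957 percentage points over 4 sets of genes. Expression of the copy of 1 parent alone, the same parent for all genes, would put Hybrid F on 1 side throughout, but at least 3 genes per tissue lay on the less frequent side by sign, 2 of them (Cfor_04911 and Cfor_05466) near that parent in both tissues. For Cfor_04911 and Cfor_05466 by themselves, which put Hybrid F with C. formosanus and Hybrid G with C. gestroi in both tissues, expression from 1 parent alone stays open, and the labels do not name the mother. Gene variants carried by the colonies used stay open. The 11 genes called in both tissues with the same sign would follow from them, but no second colony of a cross can be set beside these profiles, and untested differences between the crosses in parentage remain.

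Genes highest before the molt lie in runs of neighbouring ID numbers. Among Cfor genes highest before the molt, 90 pairs in the head and 65 in the body had consecutive numbers, against means of 14.8 and 11.7 and maxima of 30 and 26 in 10000 random lists of the same size (permutation p = 0.0001, the smallest they can give, adjusted p = 0.00018 over 24 tests). Reads shared between near-identical neighbours are argued against as the whole cause. Among genes with at least 90% whole-number counts, 57 pairs remained in the head and 40 in the body, above the highest of the random lists (23 and 20). Genes highest between molts gave 67 pairs in the head and 21 in the body. Among those with whole counts 24 remained in the head (highest of the random lists 18), but 2 in the body (mean of random lists 1.40, adjusted p = 0.45). Not all stage patterns showed such runs. Genes lowest after the molt in the body had 1 pair (adjusted p = 0.30), and among genes with whole counts those highest after the molt in the head had 5 (0.21), those lowest after the molt in the body 1 (0.17) and those lowest before the molt 1 in each tissue (0.52). Whether neighbouring numbers mean neighbouring genes on a chromosome is not known from the table, so co-regulated clusters or families of related genes may both give such runs.

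Other splits of the same profiles were fitted to see how often they give as many genes. Crosses are the blocks of the stage contrasts, so stages were swapped within crosses. These 8 splits are too few for a share under 0.05. Each swap also moves a real stage effect into the error, so low counts in the other splits were fixed in advance. They do not speak for or against chance. In the head the real values of 6456, 6216 and 3396 genes (pre-molt against inter-molt, post-molt against inter-molt, post-molt against pre-molt) stood against highest other values of 4, 1 and 1, and in the body 3455, 2668 and 1858 against 0, 0 and 0. For genes outside both parents, 40 splits were drawn within stages, and 4 of 40 gave as many in each case. The highest were 2725 and 2343 against 118 and 39 in the head and 2718 and 2598 against 181 and 70 in the body (Hybrid F and Hybrid G). In each of these C. gestroi took the place of the hybrid. These splits mix the parental species, so they do not tell whether chance gives such genes. The 10 splits of a pair of crosses are too few for a share under 0.05. A real difference between the crosses of a pair counts as error in the other splits, which keeps their counts low. The highest other splits gave 0 or 1 genes against real values of 897 to 6743 in the 10 contrasts that involve a parental species, and 0 against 19 for Hybrid G against Hybrid F in the head. In the body that contrast gave 16 genes, and 2 of 10 splits gave as many. The highest, with 73 genes, put both pre-molt profiles and the inter-molt Hybrid G profile together, and its cause was not tested. The 3 splits of the crosses for hybrid status all gave 0 genes in each tissue and are too few as well. So are the 4 splits that set 1 cross against the other 3, where the highest counts were 19 head genes for C. formosanus (highest other 7) and 28 body genes for Hybrid G (highest other 3).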

How the results depend on the processing

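Leaving out a profile, leaving out genes with NA, thinning, the filter at all stages and all settings of stage by cross were chosen after the data were seen. No paired analysis was possible because the columns of a group are identical, so the replicate numbers pair nothing; crosses and stages served as blocks in their place. Leaving out 1 of several identical columns changes nothing, so whole profiles were left out. The gene lists gave no value under any setting. Apart from stage by cross, all 32 results kept their count within 1.5 times under median-of-ratios scaling, without a filter and without genes with NA; the largest shift of the median log2 change of all genes with scaling was -0.036, in Hybrid G against C. formosanus bodies. No ID named for the stage, species and hybrid contrasts changed sign under any setting. Leaving out genes with NA removed 7 of the 72, each without a count in 1 species, so these had no test there. The comparison of head and body with its named IDs, and Cfor_09914, were not rerun. DESeq2 kept all 72 of these calls, and 50 of 864 were lost when a profile was left out and 6 of 72 with thinning.

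Apart from stage by cross, DESeq2 gave other counts for 12 of 24 results, all higher. In the head these were Hybrid G against C. formosanus 2903 and against Hybrid F 272, outside both parents 241 (Hybrid F) and 99 (Hybrid G), and hybrid status 160. In the body they were post-molt against pre-molt 3155, Hybrid F against C. formosanus 2890, Hybrid G against C. formosanus 2378 and against Hybrid F 135, outside both parents 563 and 328, and hybrid status 150. The cause was not tested. Thinning to the smallest total moved body results to 500 (Hybrid F against C. formosanus), 339 (Hybrid G against C. formosanus), 2433 (Hybrid G against C. gestroi), 5 (Hybrid G against Hybrid F), 56 and 29 (outside both parents, Hybrid F and Hybrid G), which follows from fewer counts. The hybrids alone gave 1865 and 920 body genes before and after the molt against inter-molt, with fewer profiles. Each cross alone gave 4-fold ranges within 1.5 times of the main counts. With the filter at all stages, which leaves out genes without counts at a stage, it gave 1461 (C. gestroi) and 1270 (Hybrid G) in the head and 1629 (C. formosanus), 1416 (C. gestroi) and 1427 (Hybrid G) in the body.

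Leaving out 1 profile in turn kept head stage contrasts and both species contrasts within 1.5 times. Other counts ranged as follows. In the head: Hybrid F against C. formosanus 884 to 2669 and against C. gestroi 2778 to 4729, Hybrid G against C. formosanus 829 to 2084, against C. gestroi 2120 to 3925 and against Hybrid F 5 to 22, outside both parents 19 to 148 and 13 to 39, hybrid status 0 to 15 (without inter-molt Hybrid F). In the body: pre-molt against inter-molt 2164 to 3362, post-molt against inter-molt 1384 to 2994, post-molt against pre-molt 785 to 2035, Hybrid F against C. formosanus 403 to 1905 and against C. gestroi 2401 to 4549, Hybrid G against C. formosanus 371 to 1111, against C. gestroi 1903 to 3672 and against Hybrid F 3 to 13, outside both parents 21 to 206 and 20 to 77. Each left-out profile removes a residual degree of freedom and 1 of 3 or 4 values of a group. Depth limits low genes: at the smallest totals a gene without counts may stand at up to 0.304 CPM (total without TMM scaling).

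Stage by cross over both tissues (296 genes) gave 1764 by DESeq2 and 140 with tissue as the only block term, and 84 to 387 when a profile was left out. It stayed within 1.5 times under median-of-ratios scaling, without a filter, without genes with NA and with thinning, as did the stage counts of each single cross, also under DESeq2. Leaving out a profile gave 3092 to 5061 for the stages of C. formosanus, 3003 to 4305 for C. gestroi, 2123 to 4328 for Hybrid F and 2092 to 4079 for Hybrid G. For 1 cross against the other 3, Hybrid G heads (7 genes) gave 14 under median-of-ratios scaling, 15 without a filter, 16 without genes with NA and 14 with thinning. C. gestroi bodies (2 genes) gave 1 under median-of-ratios scaling and with thinning, and C. formosanus bodies (3 genes) gave 0 with thinning. DESeq2 gave 451, 436, 45 and 188 head genes and 274, 699, 7 and 283 body genes (C. formosanus, C. gestroi, Hybrid F, Hybrid G).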

Other observations

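The comparison of head and body was chosen after the data were seen. Over the 12 pairs of head and body profiles from the same cross and stage, edgeR (paired, 11 residual degrees of freedom) called 3097 of 12416 genes higher in the head and 2667 higher in the body, of which 38 and 166 by at least 16-fold. Cfor_10175 stood at 203.1 ± 163.3 CPM in heads and 0.907 ± 0.682 CPM in bodies (SD, n = 12 profiles), a log2 difference of 7.47 ± 0.71 (edgeR adjusted p = 2.1e-06). BGI_novel_G003323 stood at 989.9 ± 1247 CPM in heads and 8.59 ± 10.3 CPM in bodies. In the other direction Cfor_09069 stood at 1401 ± 2056 CPM in bodies and 0.578 ± 0.867 CPM in heads, and Cfor_07052 at 1948 ± 3152 and 0.585 ± 0.630 CPM.

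Genes with at least 5 CPM in the heads of 1 species and at most 3 counts in those of the other were examined in the hybrids, also after the data were seen. The 80 head genes found in C. formosanus alone had medians of 47.8% (95% bootstrap interval over genes 41.4% to 53.7%) of the parental level in Hybrid F and 47.9% (39.1% to 55.2%) in Hybrid G. The 36 found in C. gestroi alone had medians of 44.2% and 44.0%. In the body, 120 and 43 such genes had medians of 42.9% and 43.6% (C. formosanus) and 42.2% and 43.6% (C. gestroi). In the other species 72 of 80 and 32 of 36 head genes and 109 of 120 and 40 of 43 body genes had an NA, so these sets rest on NA read as no reads. Genes are not independent replicates, and no explanation was tested.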
